A study of Homo sapiens with 6 samples.

How the data were processed

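The data are 6 poly(A)-selected, strand-specific RNA-seq libraries of the HBL-1 lymphoma line, 3 treated with 0.05% DMSO and 3 with the compound at 5 µM (RO in the labels). The labels call them biological replicates and do not say more about how the cultures were kept apart, so p-values measure the spread between these libraries. The authors deposited one table of raw counts per Ensembl transcript. It lists 143966 transcripts, of which 125460 have a value above 0, with gene identifiers, biotypes and symbols. Per the submitters' processing notes, FastQC 0.11.9, fastp 0.23.2, SAMtools 1.16.1, STAR 2.7.11a, Bowtie2 2.5.3 and Salmon were used with the genome build GRCh38.p14. The notes give no roles, so which tool made the counts, and whether strand was used, is not given in the sources used here.

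The deposited values are whole numbers, but they behave like estimated counts, the unit used here, whose decimal point was lost. Each library's deposited values sum to many times any usual sequencing depth. Of 310190 values of 10000 or more, 2 end in 0, as happens when trailing zeros of decimals are dropped before the point is removed. A deposited value can thus stand for itself or for itself divided by 10, 100 or 1000. How the point was lost is not given in the sources used here, and the design written before the data were examined did not foresee it. The point was put back in 2 steps that did not use the treatment labels. In step 1, each transcript's 4 possible readings were weighed against its level in the other libraries, allowing any of the 10 splits of the libraries into 3 and 3 to have different levels (total probability 0.1). In step 2, readings were weighed by whether the transcripts of a gene add up to a whole number of reads, and by how near the gene total lay to that of any other library. Mitochondrial transcripts whose deposited values lay within 2-fold of each other and from 1000 to below 1000000 in all libraries were read as whole numbers (4 transcripts). After step 1, which uses no totals, 45.3% of 69412 gene and library totals were whole to within 0.0005 per transcript, against 0.753% by chance, and after step 2 57.0% were. Among step 1 estimates of 100 to 1000 reads, 91.3% had 3 decimals, 7.88% had 2 and 0.798% had 1, where 90%, 9% and 0.9% would follow from evenly spread digits. Step 2 moved 2.21% of the values. Below, a gene is said to have whole totals where its totals after step 2 were whole in every library that could be checked. The check needed at least 2 deposited values of 1000 or more for a gene and library, so some genes without a check are included.

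Transcripts were summed to genes by symbol, or by Ensembl gene where no symbol was given, and rounded to whole numbers. A gene was taken as unsettled, and left out of the tests, where the readings within 25% of the best total held a probability under 0.8 in any library. This concerned 600 of 13777 genes with a mean of at least 20 counts (4.36%), and unsettled genes held 1.42% of all counts. Restored totals were 25633952 to 30563798 counts per library, and mitochondrial genes held 3.29% to 4.61%. The table does not list every transcript of every gene, so gene totals are sums over the listed transcripts. Genes that share sequence with copies or overlap other genes carry added uncertainty, since estimated counts split shared reads.

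Restoring was tested on simulated data with a known truth (8000 genes, gene totals drawn from the real means, 200 genes changed). Totals were split among transcripts as in the restored real libraries, so the test is not independent of the restoring and may overstate its accuracy. It placed 97.8% of values right and settled 96.3% of genes of 20 or more counts. Of the single-library totals of these settled genes, 98.5% were within 10% of the truth and 0.284% were more than 2-fold off. On the restored simulated table, edgeR without the block recovered 72.9% of 48 genes changed 1.5-fold and 100% of 44 genes changed 2-fold and of 44 changed 4-fold, the same as on the true table. Of 30 genes changed 10-fold it recovered 46.7%, against 100% on the true table. A 10-fold change and a moved decimal point look alike, so changes near 10-fold can be missed in the real data. These shares are over the settled genes that also passed the filter on low counts, out of 7608 settled genes. The fold classes began equal in size, and 48, 44, 44 and 30 genes were left at 1.5-, 2-, 4- and 10-fold. More 10-fold changes than others thus never reached the test, and the 46.7% leaves these out. Of the calls made, 2.84% were unchanged genes without the block and 6.80% with it. Every simulated gene had the same dispersion, and same-numbered libraries shared no differences, unlike the real ones. The recovered shares and these rates hold for that setting only. The 6.80% is therefore not an error rate for the real calls with the block. A set of 20 genes of which 10 were raised 1.5-fold had a camera p of 1.05e-06, and 1% of 200 unchanged sets had p below 0.05. The simulated genes varied independently of each other, while real lists had estimated correlations of up to 0.94 (G2/M and mitosis). The simulation therefore cannot show how often unchanged real lists would pass at the preset correlation of 0.01.

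Genes were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM factors, filterByExpr), with RO against DMSO as the only term and Benjamini-Hochberg adjustment over 14690 genes at 0.05. Standard errors are the log2 fold change divided by the square root of its F value, and 95% confidence intervals use the test's total degrees of freedom. The fit has 4 residual degrees of freedom per gene before moderation, and 2 with the replicate block. CPM use TMM factors, and error terms are SD over 3 libraries. The biological coefficient of variation was 0.0904, or 0.0534 with the replicate block. Fold changes against a group with 0 counts in all libraries are given against a floor of 3 counts per library, which covers counting error only.

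The labels number the replicates 1 to 3 in both groups. Deviations from the group means of same-numbered libraries correlated at 0.64, 0.18 and 0.41 (genes with a mean log2 CPM of at least 3), all above 0.1, against at most -0.32, 0.22 and 0.22 between DMSO replicates 1, 2 and 3 and a differently numbered RO library, and the first principal component, with 44.7% of the variance, set replicate 1 of both groups apart from the rest. The numbers were therefore taken to pair the libraries. The result of the fit with the replicate number as a block is printed beside the results of the text whose call it changes. The second principal component, with 22.0% of the variance, set all DMSO libraries (-0.52 to -0.31) apart from all RO libraries (0.29 to 0.52).

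The 36 gene lists (735 genes) were fixed before the data were examined. Of their genes 615 were tested, 39 were unsettled and 23 were not listed in the table. Lists with at least 4 tested members (32) were tested with camera from limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided), with Benjamini-Hochberg adjustment over the lists. fry tests whether a list's genes move on balance one way, and does not compare the list with other genes. None of the 5 lists called at the preset correlation passed with an estimated one. Named genes were chosen by a fixed rule. It takes the 12 genes with the largest changes in each direction among called genes with a mean log2 CPM of at least 1, separate groups and a proper symbol. It adds genes given in advance (among them MSI1, MSI2, NGFR, SORT1, DNA damage response genes, CDKN1A and MYC) and the 4 members of each list with the smallest p. Applying the first part also to the fit with the replicate block, and naming list members called there, was decided after seeing the data. Some genes given in advance and 1 of the lists are not reported here. Coordinates are those of RefSeq on GRCh38.p14.

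Alternatives planned before the data were examined were RLE and upper-quartile factors, no filter on low counts, a mean of at least 10 counts, DESeq2 1.42.0, limma-voom, the replicate block, leaving out each library, nuclear genes only, a glmTreat test against 2-fold, an estimated correlation and fry. Added after seeing the data were the values as deposited, division of every value of 1000 or more by 1000, restoring that knows the treatment split, 20 random draws of the point from its probabilities, keeping unsettled genes, using only genes with whole totals, leaving out both replicate 1 libraries, and combinations with the block. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for restoring and figures.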

Results

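Messenger RNA was sequenced from HBL-1 cells, an established human line of the activated B-cell-like type of diffuse large B-cell lymphoma whose growth is known to rely on B-cell receptor and NF-kB signalling. The compound under study, shortened to RO in the labels, is a small molecule described as a blocker of signalling at the p75 neurotrophin receptor and later as an inhibitor of RNA binding by Musashi proteins. Cells received the compound at 5 µM, or its solvent DMSO at 0.05%, on 2 occasions, 24 h and 5 h before collection. Each group held 3 libraries labelled as biological replicates, and the labels name no irradiation for these 6 libraries. The study's title concerns radiation toxicity and the DNA damage response, so the comparison asks which transcripts, and above all which DNA damage response transcripts, the compound alone altered. Restored totals were 25633952, 25641488 and 30563798 counts in DMSO replicates 1, 2 and 3, and 28078116, 26874555 and 26443849 counts in RO replicates 1, 2 and 3. Between 15274 and 15652 genes per library had at least 10 counts.

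The response was small, and antioxidant genes stood out in it. Of 14690 genes tested, 4 passed an adjusted p of 0.05, 3 of them higher and 1 lower after RO, and 975 had an unadjusted p below 0.05. TXNRD1, which encodes thioredoxin reductase 1, an enzyme of the thioredoxin antioxidant system, rose from 430 ± 10.8 to 581 ± 19.0 CPM (counts scaled to library size; mean ± SD, n = 3 each; log2 fold change 0.43, SE 0.04, edgeR adjusted p = 0.0383). WDR74, which encodes a ribosome assembly factor, fell from 97.9 ± 1.21 to 74.4 ± 1.08 CPM (SD, n = 3 each; log2 fold change -0.40, SE 0.04, edgeR adjusted p = 0.0383). TXNRD1 (ENSG00000198431) lies on chromosome 12 at positions 104215779 to 104350307 and WDR74 (ENSG00000133316) on chromosome 11 at 62832905 to 62841809 of GRCh38.p14. The other calls were outside the rule for named genes and were noted after their values were seen. ENSG00000285646, an uncharacterised non-coding RNA gene, had 17, 15 and 17 counts in the DMSO libraries and 70, 66 and 67 in the RO libraries. CORO7-PAM16, a readthrough gene that overlaps CORO7 and PAM16, had 0 counts in all 3 DMSO libraries and 90, 78 and 47 rounded counts in the RO libraries, at least 23.9-fold higher against a floor of 3 counts per library. These last 2 were the calls over 2-fold, and CORO7 and PAM16 themselves had log2 fold changes of -0.12 (SE 0.06) and -0.02 (SE 0.11). Reads of an overlapping gene cannot be assigned to it with certainty. In 20 random draws of the restored decimal points 0 to 1 genes passed, so at least 3 of the 4 calls were lost in each draw, and the log2 fold change of WDR74 lay between -0.45 and -0.09 (edgeR adjusted p = 0.154 and 0.959). With the replicate number as a block, 93 genes passed, 42 higher and 51 lower, 6 of them over 2-fold and including all 4 genes above. With the block and without both libraries of replicate 1, 2 or 3 there were 1, 129 and 77, so nearly all calls with the block were lost without replicate 1. DESeq2 without the block called 47, including the same 4. The count without the block was 0 when any 1 of the 6 libraries was left out, with edgeR adjusted p values of 0.0983 to 0.188 for TXNRD1, whose log2 fold change stayed between 0.41 and 0.46.

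**Figure D1:**
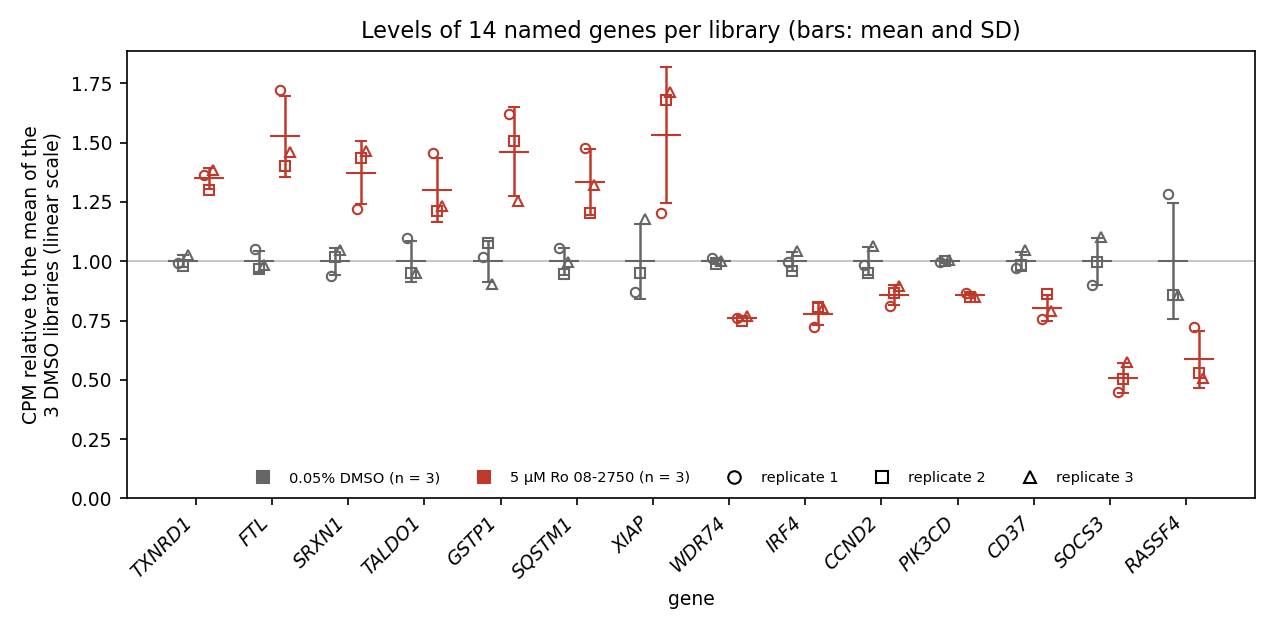
CPM of 14 named genes in each library, divided by the mean of the 3 DMSO libraries of that gene (linear axis). Points are libraries, with the replicate number as the shape, and bars give mean and SD (n = 3 per group). TXNRD1 and WDR74 passed the test without the replicate block, the other 12 with it. All 3 RO libraries lay above the DMSO libraries for the first 7 genes and below them for the last 7.

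Antioxidant genes controlled by the transcription factor NRF2 were the group with the clearest change. All 19 measured members of this list were higher after RO, with a median log2 fold change of 0.28, and the list rose by the camera test (adjusted p = 7.40e-14 at a preset correlation of 0.01). The adjusted p = 0.0858 with an estimated correlation did not pass, while the directional fry test did (adjusted p = 0.0166). At the preset correlation, camera also called this list in other splits of the libraries into 3 and 3. These set DMSO replicates 1 and 2 and RO replicate 2 apart (camera adjusted p = 0.00175), or DMSO replicate 1 and RO replicates 1 and 3 (camera adjusted p = 0.00283). The medians there were 0.12 and -0.18, smaller in size than 0.28. TXNRD1 was the only member called over all genes and 11 members were called higher when adjusted over the list alone. With the replicate block these counts were 8 and 14. NQO1, the member with the largest change (log2 fold change 0.78, SE 0.27), was called in neither model (edgeR adjusted p = 0.625, 0.208 with the block). Its levels were 12.4 and 12.5 CPM in DMSO and RO replicate 3. Ferritin light chain, FTL, an iron storage protein, went from 661 ± 29.7 to 1010 ± 113 CPM (SD, n = 3 each; log2 fold change 0.61, SE 0.08, edgeR adjusted p = 0.0762, 0.00213 with the block). SRXN1, which reduces oxidised peroxiredoxins, had a log2 fold change of 0.46 (SE 0.08, adjusted p = 0.219, 0.0142 with the block). TALDO1, a pentose phosphate pathway enzyme, had one of 0.38 (SE 0.09, adjusted p = 0.412, 0.00631 with the block). The heme oxygenase gene HMOX1 (edgeR adjusted p = 0.0172 with the block), thioredoxin TXN (0.0269), ferritin heavy chain FTH1 (0.0104) and glutathione reductase GSR (0.0346) were the further members called higher with the block. Outside the list, glutathione transferase GSTP1 had a log2 fold change of 0.55 (SE 0.10, adjusted p = 0.245, 0.0104 with the block). The mean log2 difference of the list between RO and DMSO was 0.35, 0.32 and 0.29 in replicates 1, 2 and 3.

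Genes of the integrated stress response, driven by the transcription factor ATF4, were higher in 23 of 24 members, with a median log2 fold change of 0.18. The list rose by camera at the preset correlation (adjusted p = 2.73e-05). It did not pass with an estimated one (camera adjusted p = 0.624) or by fry (adjusted p = 0.356, 0.234 with the block). No member was called over all genes or adjusted over the list alone without the block. With it, the amino acid transporter subunit SLC3A2 (log2 fold change 0.28, SE 0.07, edgeR adjusted p = 0.0284 with the block) was called over all genes and 10 members were called higher adjusted over the list alone. ATF4 itself had a log2 fold change of 0.21 (SE 0.07) and the pseudokinase TRIB3 one of 0.23 (SE 0.07), neither passing over all genes in either model. The autophagy and lysosome list had 17 of 22 members higher and a median of 0.10. It rose by camera at the preset correlation only (camera adjusted p = 0.000956, 0.624 with an estimated correlation, fry adjusted p = 0.356). The autophagy receptor SQSTM1, itself an NRF2 target, accounted for the call in this list adjusted over the list alone (1 member, 4 with the block) and went from 493 ± 27.9 to 657 ± 68.5 CPM (SD, n = 3 each; log2 fold change 0.42, SE 0.08, edgeR adjusted p = 0.257, 0.00421 with the block). Lysosomal membrane protein LAMP2 had a log2 fold change of 0.15 (SE 0.04) and the sialidase NEU1 one of 0.22 (SE 0.07), neither passing over all genes. Nuclear-encoded respiratory chain genes were higher in 25 of 29 members, with a median of 0.05. This list rose by camera at the preset correlation only (camera adjusted p = 0.00265, 0.826 with an estimated correlation, fry adjusted p = 0.356). Its members NDUFB3 and NDUFB5, subunits of complex I, had log2 fold changes of 0.18 (SE 0.05) and 0.21 (SE 0.07), and no member passed over all genes, while 1 was called higher with the block when adjusted over the list alone. This call was lost without DMSO replicate 1 (adjusted p = 0.0949), and, like that of the autophagy and lysosome list, when only genes with whole totals were used (adjusted p = 0.271 and 0.0836). Cytosolic ribosomal protein genes were higher in 29 of 29 members by a median of 0.05, a change called with the replicate block (camera adjusted p = 0.000547, adjusted p = 0.758 with an estimated correlation) and not without it (adjusted p = 0.0732). Without the block it passed when DMSO replicate 1 (adjusted p = 8.92e-05), RO replicate 2 (adjusted p = 0.00903) or RO replicate 3 (adjusted p = 0.00568) was left out, and its direction turned without RO replicate 1 (adjusted p = 0.731). No member was called over all genes in either model, and 14 were called higher with the block when adjusted over the list alone. Relative to the DMSO mean, this list had mean log2 levels of 0.12 and 0.19 in DMSO and RO replicate 1 and of -0.08 to -0.01 in the other 4 libraries, a gap larger than the change. RPL5 had a log2 fold change of 0.08 (SE 0.06).

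NF-kB target genes fell as a list by camera at the preset correlation only. Of 25 members 23 were lower, with a median log2 fold change of -0.19 (camera adjusted p = 0.000956, adjusted p = 0.932 with an estimated correlation). The camera call was lost without DMSO replicate 1 (adjusted p = 0.169) and without RO replicate 2 (adjusted p = 0.0518). The fry test did not pass (adjusted p = 0.642, 0.209 with the block). The mean log2 difference of the list between RO and DMSO was -0.15, 0.00 and -0.17 in replicates 1, 2 and 3, and the chemokine gene CCL3, one of 2 members with a higher level, had a log2 fold change of 0.90. No member was called over all genes and 3 were called lower adjusted over the list alone. With the block these were 4 and 14. IRF4, a transcription factor on which activated B-cell-like lymphoma lines depend, went from 524 ± 21.4 to 407 ± 25.3 CPM (SD, n = 3 each; log2 fold change -0.36, SE 0.06, edgeR adjusted p = 0.145, 0.0170 with the block). Cyclin D2, CCND2, had a log2 fold change of -0.22 (SE 0.06, adjusted p = 0.499, 0.0269 with the block), and the NF-kB subunit RELB one of -0.30 (SE 0.11), which passed in neither model. BIRC3 (edgeR adjusted p = 0.0490 with the block) and PIM1 (0.0231) were the other members called lower with the block. The B-cell receptor list (17 of 24 members lower, median -0.04, camera adjusted p = 0.0816) and the B-cell and germinal centre identity list (13 of 20 lower, median -0.08, adjusted p = 0.0932) did not pass, with 2 members each called lower adjusted over the list alone. With the block 2 members of the B-cell receptor list were called higher and 4 lower, and 6 of the identity list lower. The B-cell receptor list passed without RO replicate 1 (adjusted p = 0.00151). In these lists the kinases PIK3CD (log2 fold change -0.22, SE 0.04, edgeR adjusted p = 0.180, 0.0310 with the block) and LYN (-0.16, SE 0.04, adjusted p = 0.484, 0.0474 with the block), the tetraspanin CD37 (-0.32, SE 0.06, adjusted p = 0.233, 0.0242 with the block) and the transcription factor SPIB (-0.16, SE 0.06, adjusted p = 0.722, 0.0377 with the block) were called with the replicate block. BCL11A, with a log2 fold change of -0.18 (SE 0.04), passed in neither model.

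Genes of G2/M and mitosis were lower in 27 of 30 members by a median of -0.08. This list was called with the replicate block (camera adjusted p = 5.12e-05, adjusted p = 0.758 with an estimated correlation) and not without it (adjusted p = 0.102). Without the block it passed when DMSO replicate 1 (adjusted p = 7.59e-06), RO replicate 2 (adjusted p = 0.00966) or RO replicate 3 (adjusted p = 0.00781) was left out, and its direction turned without RO replicate 1 (adjusted p = 0.311). Relative to the DMSO mean, this list had mean log2 levels of -0.22 and -0.32 in DMSO and RO replicate 1 and of 0.03 to 0.12 in the other 4 libraries. TOP2A, topoisomerase 2-alpha, had a log2 fold change of -0.12 (SE 0.10) and HMMR, a mitotic spindle protein, one of -0.20 (SE 0.09), and no member passed over all genes in either model, while 10 were called lower with the block when adjusted over the list alone. G1/S and DNA replication genes (21 of 30 lower, median -0.03) had an adjusted p of 0.115, and 0.0363 without RO replicate 2.

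No DNA damage response list was called. None of the 7 lists passed the camera test with or without the replicate block, with an estimated correlation, or by fry, and none of their members was called over all genes by edgeR without or with the block. DNA damage checkpoint signalling came closest, with 17 of 23 members lower, a median log2 fold change of -0.05 and an adjusted p of 0.194. The medians were 0.01 for homologous recombination (26 members, adjusted p = 0.934), -0.03 for non-homologous end joining (16 members, adjusted p = 0.737), -0.02 for the Fanconi anaemia pathway (16 members, adjusted p = 0.419), 0.04 for base excision repair (15 members, adjusted p = 0.615) and -0.01 for nucleotide excision and mismatch repair (15 members, adjusted p = 0.737). Adjusted over the list alone, 0 members of the 7 lists passed without the block and 1 each in 3 of them with it, among these the checkpoint list (lower) and the Fanconi anaemia list (higher). By edgeR, unadjusted p values below 0.05 were found, in the 6 lists with medians given here, for 2 of 23 checkpoint members, MDC1 and ETAA1, 3 Fanconi anaemia members and 2 base excision repair members. The mediator protein gene MDC1 had a log2 fold change of -0.29 (95% confidence interval -0.53 to -0.05, adjusted p = 0.682, 0.0594 with the block) and the ATR activator gene ETAA1 one of -0.21 (95% confidence interval -0.38 to -0.04, adjusted p = 0.643, 0.175 with the block). The apical kinase genes ATM, ATR and PRKDC had log2 fold changes of -0.07, -0.08 and -0.07 with intervals of -0.34 to 0.21, -0.22 to 0.06 and -0.32 to 0.18. CHEK1 was at 0.01 (-0.12 to 0.14) and CHEK2 at -0.03 (-0.23 to 0.18). BRCA1 was at -0.05 (-0.21 to 0.11), BRCA2 at -0.05 (-0.25 to 0.14) and H2AX at -0.03 (-0.38 to 0.31). In the draws of the decimal points CHEK2 reached 1.71 at the highest, so its value rests on the restoring. The cell cycle inhibitor gene CDKN1A, reported as bound by Musashi proteins, went from 53.7 ± 4.45 to 67.0 ± 9.22 CPM (SD, n = 3 each; log2 fold change 0.32, edgeR adjusted p = 0.593, 0.0530 with the block). With no filter on low counts, CDKN1A (edgeR adjusted p = 0.0216) and MDC1 (adjusted p = 0.0460) passed. The intervals exclude 2-fold changes of these transcripts, apart from the uncertainty of restoring, and leave smaller ones open.

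**Figure D2:**
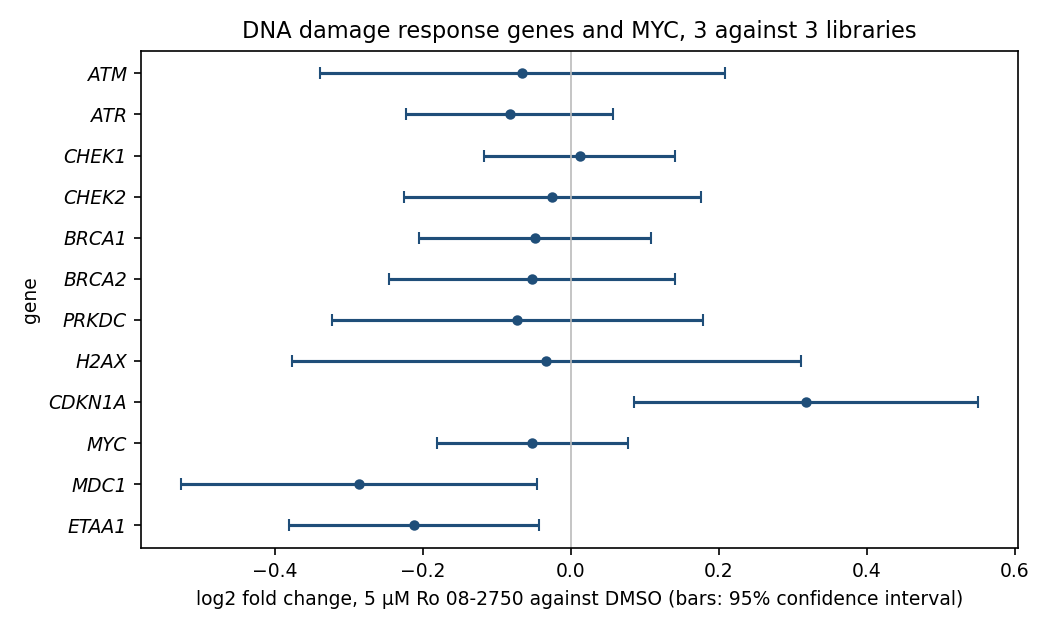
Log2 fold change between 5 µM RO and DMSO (x axis, 3 against 3 libraries) of 11 DNA damage response genes and MYC (y axis). Points are edgeR estimates and bars 95% confidence intervals. The intervals of CDKN1A, MDC1 and ETAA1 exclude 0 and those of the other 9 genes include it. None passed after adjustment over all genes.

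Reported targets of the compound were looked up next. MSI2 was expressed at 94.5 ± 6.43 CPM in DMSO and 94.6 ± 3.08 CPM in RO libraries (SD, n = 3 each; log2 fold change 0.00, 95% confidence interval -0.13 to 0.13), while MSI1 averaged 0.3 counts per library and was not tested. NGFR, the p75 neurotrophin receptor gene, was near the detection limit, with 0.375 ± 0.0568 and 0.402 ± 0.273 CPM (SD, n = 3 each). The neurotrophin and p75NTR signalling list (9 of 16 members tested, median 0.05, camera adjusted p = 0.215) did not pass. Neither did the list of reported Musashi-bound transcripts (5 of 9 members tested, median -0.05, camera adjusted p = 0.934, 1 member called higher with the block adjusted over the list alone). Its members NUMB and TGFBR1 were unsettled and left out, so the test does not cover all reported targets. The sorting receptor SORT1 had a log2 fold change of 0.18 (SE 0.05, edgeR adjusted p = 0.513, 0.0894 with the block) and was called in its list adjusted over the list alone. MYC had one of -0.05 (95% confidence interval -0.18 to 0.08).

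The remaining lists did not pass the camera test in either model with all 6 libraries. Median log2 fold changes were 0.02 for ribosome biogenesis and MYC targets (adjusted p = 0.419), 0.03 for the endoplasmic reticulum unfolded protein response (adjusted p = 0.0732), 0.00 for the heat shock response (adjusted p = 0.934), 0.00 for aryl hydrocarbon receptor targets (adjusted p = 0.548), -0.01 for cholesterol biosynthesis (adjusted p = 0.934) and 0.03 for glycolysis and hypoxia (adjusted p = 0.419). They were 0.09 for plasma cell differentiation (adjusted p = 0.615), 0.06 for antigen presentation (adjusted p = 0.934), 0.16 for interferon-stimulated genes (adjusted p = 0.615), -0.05 for the BCL2 family and apoptosis (adjusted p = 0.805) and 0.01 for immediate early genes (adjusted p = 0.890). They were -0.10 for the mitochondrially encoded respiratory chain (adjusted p = 0.612) and -0.05 for replication-dependent histones (adjusted p = 0.805). Leaving out 1 library gave a call for the unfolded protein response (without RO replicate 1, adjusted p = 0.0434), cholesterol biosynthesis (without DMSO replicate 3, adjusted p = 0.0486) and the mitochondrially encoded respiratory chain (without DMSO replicate 2, adjusted p = 0.000122). The mean log2 differences between RO and DMSO in replicates 1, 2 and 3 were 0.20, 0.03 and 0.00 for interferon-stimulated genes and 0.09, 0.06 and -0.03 for antigen presentation, and both turned in direction without RO replicate 1 (adjusted p = 0.275 and 0.311). Leaving out 1 library, in at least 1 of the 6 cases, also turned the direction for cholesterol biosynthesis, including its call, glycolysis and hypoxia, heat shock, apoptosis, immediate early, mitochondrially encoded respiratory chain and histone genes, and for homologous recombination, Fanconi anaemia, G1/S and Musashi-bound genes. In 4 lists, homologous recombination, heat shock response, BCL2 family and apoptosis, and immediate early genes, the median, the mean and the direction of the test differed in sign. Within the apoptosis list the caspase inhibitor gene XIAP went from 44.7 ± 7.08 to 68.6 ± 12.8 CPM (SD, n = 3 each; log2 fold change 0.61, SE 0.15, edgeR adjusted p = 0.484, 0.0184 with the block). BMF, a cell death activator gene (-0.25, SE 0.10, adjusted p = 0.723, 0.0377 with the block), and BIRC3 (-0.22, SE 0.10, adjusted p = 0.761, 0.0490 with the block) were called lower with the block, and BCL2 had a log2 fold change of 0.15 (SE 0.05), not called in either model. Besides IRF4, also a member of the plasma cell list, other members called over all genes with the block were the glycolytic enzyme gene GAPDH (higher, edgeR adjusted p = 0.0490 with the block), the immediate early gene EGR1 (higher, 0.0377) and the mitochondrial gene MT-CO1 (lower, 0.0413). Adjusted over the list alone, 1 member of the plasma cell list was called lower without the block. With it, 4 glycolysis and 3 antigen presentation members and 1 each in the unfolded protein response, interferon and immediate early lists were called higher, 3 mitochondrially encoded members lower, 2 apoptosis members higher and 3 lower, and 1 plasma cell member higher and 1 lower. Lists with fewer than 4 tested members were not tested. Their medians were 0.02 for metallothioneins and zinc export (3 members), -0.05 for T-cell and NK-cell markers (2 members) and 0.14 for stromal, epithelial and endothelial markers (2 members, 1 called higher with the block adjusted over the list alone), and 0 of 13 myeloid markers were tested.

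**Figure D3:**
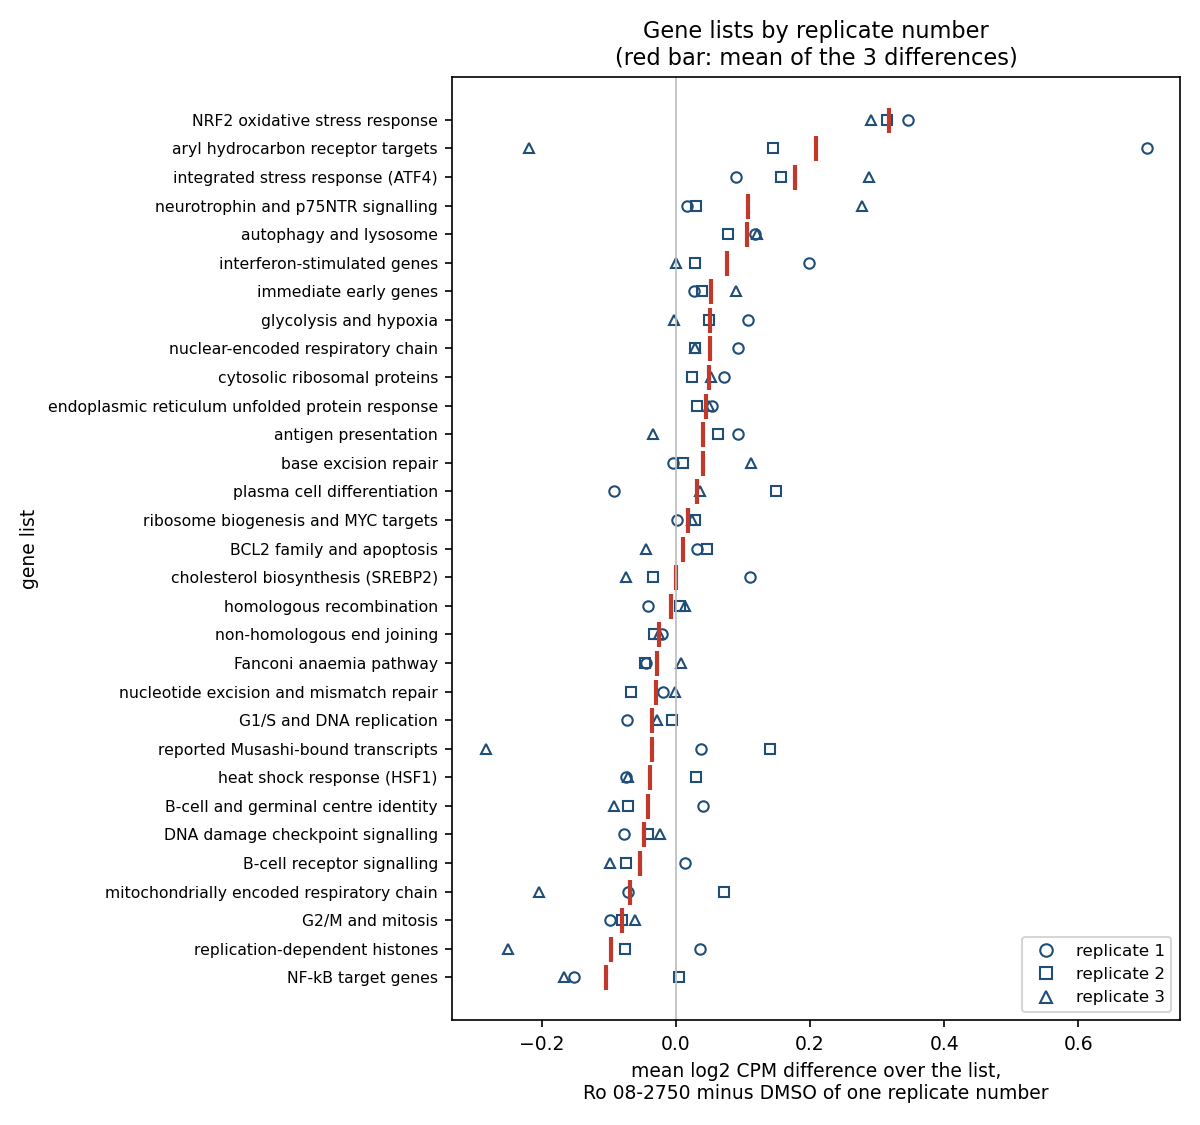
Mean difference over the list in log2 CPM between the RO and the DMSO library of the same replicate number (x axis) for 31 of the 32 tested gene lists (y axis). Shapes are the 3 replicate numbers and red bars their mean. The NRF2 list lies at 0.35, 0.32 and 0.29, and the aryl hydrocarbon receptor list, with 5 members, spreads from -0.22 to 0.70.

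Among genes outside the called lists, several were named by their size of change in the model with the replicate block, and some of them are described here. SOCS3, a feedback inhibitor of cytokine signalling, went from 15.8 ± 1.58 to 8.07 ± 1.01 CPM (SD, n = 3 each; log2 fold change -0.97, SE 0.12, edgeR adjusted p = 0.0719, 0.00631 with the block). RASSF4 had a log2 fold change of -0.77 (SE 0.19, adjusted p = 0.476, 0.00421 with the block) and the granule protease gene GZMB one of -0.51 (SE 0.08, adjusted p = 0.105, 0.0356 with the block). The microtubule protein gene MAP1A had one of 1.23 at a low level, from 2.23 ± 0.204 to 5.24 ± 0.253 CPM (SD, n = 3 each; SE 0.15, edgeR adjusted p = 0.0719, 0.0269 with the block), and the adaptor gene DOK3 one of 0.51 (SE 0.07, adjusted p = 0.0769, 0.0142 with the block). Every RO library lay beyond the DMSO library of the same number in these 5 genes. The rule also took larger changes than some of these. Among them were SNORD3B-2 (log2 fold change 1.38, SE 0.16, edgeR adjusted p = 0.0631, 0.0184 with the block) and SP6 (-0.96, SE 0.17, adjusted p = 0.206, 0.0435 with the block). CFAP46, CKB, FRMD4A, ADAM8, LRRC32 and TNFAIP2 also fell by more than GZMB and are not described further.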

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

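Other readings of the deposited values, the handling of uncertain totals, leaving out both replicate 1 libraries, combinations of the block with another choice and all counts of list members under alternatives were chosen after seeing the data. RLE and upper-quartile factors moved the median of all genes by 0.00072 and -0.0035 log2 units. Those factors, a mean of at least 10 counts and nuclear genes only gave 4 genes each, 3 higher and 1 lower. Without a filter there were 184 genes (87 higher, 97 lower), 69 over 2-fold. DESeq2 gave 47 (9 over 2-fold, 9 in lists), limma-voom 6 (4 over 2-fold) and glmTreat 0 over 2-fold. The replicate block gave 93 (6 over 2-fold, 23 in lists) and 7 lists, and 41 of its genes were among the 47 of DESeq2. DESeq2 with the block gave 142 genes, 0 over 2-fold. Among the lists and the genes whose fold changes are printed, the block changed no call other than those given with blocked values. Leaving out each library in turn gave 0 genes, 0 over 2-fold and 0 in lists each time, with fewer libraries in the fit, and 5 to 7 lists. With the estimated correlation 0 lists passed with or without the block, and with fry 1 did.

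The values as deposited gave 21 genes, 21 over 2-fold, and 3 lists. Division of values of at least 1000 by 1000 gave 7, 7 and 3. Restoring that knew the treatment split gave 9 genes, 6 over 2-fold. Keeping unsettled genes gave 6, with 4 over 2-fold. Using only genes with whole totals, as defined above, gave 9 genes, 5 over 2-fold, and 3 lists, with fewer genes tested. This set holds some genes whose totals could not be checked and are not whole, CORO7-PAM16 among them. The 20 draws gave 0 to 1 genes and 0 to 1 over 2-fold. Without both replicate 1 libraries 1 gene, 0 over 2-fold, and 8 lists passed. With the block and without replicate 1, 2 or 3 there were 1, 129 and 77 genes, 0, 23 and 22 over 2-fold, and 6, 8 and 7 lists. The cause of these differences was not tested. The DNA damage response lists gave 0 calls under every alternative run.

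Of 833 values of 49 named genes under alternatives, 739 kept direction and side of the threshold, 16 fell short of it, 53 passed it and 25 changed sign, in 10 genes. Only TXNRD1 and WDR74 among these genes were called without the block, so only their values could fall short. Each of them did so in 8 of 17 alternatives. Leaving out libraries gave log2 fold changes of -0.031 to 0.058 for MSI2, -0.43 to 0.54 for NGFR, -0.18 to 0.020 for ATM, -0.031 to 0.046 for CHEK1, -0.096 to 0.038 for CHEK2, -0.098 to 0.012 for BRCA1, -0.12 to 0.021 for BRCA2, -0.16 to 0.058 for PRKDC and -0.18 to 0.085 for H2AX. MSI2 was at -0.0026 with upper-quartile factors and NGFR at -0.19 with limma-voom. In the draws the lowest values were -0.00033 for MSI2 and -0.040 for NGFR, and the highest 0.079 for ATM, 0.13 for ATR, 1.71 for CHEK2 and 0.027 for BRCA1. The cause was not tested.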

Other observations

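The tests of restoring, library size and the variance between replicate numbers were chosen after the results were seen. Libraries with the same replicate number resembled each other across the groups in replicates 1 and 3, while in replicate 2 the DMSO library correlated more with an RO library of another number (0.22 against 0.18). Interferon-stimulated genes had mean log2 levels of 0.62, -0.21 and -0.29 in replicates 1, 2 and 3, relative to the DMSO mean and averaged over the DMSO and RO library of each number. Immediate early genes had 0.45, -0.09 and -0.28, and G2/M genes -0.27, 0.07 and 0.08. DNAAF4-CCPG1, a second readthrough gene, chosen after its values were seen, had 0 counts in the DMSO libraries and 57, 52 and 24 in the RO libraries, at least 14.8-fold higher against a floor of 3 counts per library. It did not pass without the replicate block (edgeR adjusted p = 0.0769) and passed with it (adjusted p = 0.0245).

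The rise of NRF2 target genes was set against 3 technical explanations. Restoring of the decimal point as the whole cause was set against the 11 members with whole totals, whose median log2 fold change was 0.28 (SE 0.08). Step 2 of the restoring itself favoured whole totals and totals near those of other libraries, so these members cannot exclude it. Library size is argued against by replicate 3, where the RO library was the shallower one and the list was still higher by a mean of 0.29 (SE 0.05 over 19 members). The replicate 1 pair, which stood apart, is argued against by a median of 0.30 (SE 0.06) without both its libraries. These standard errors are over list members, which can move together, and hold no spread between cultures. The replicate 3 value rests on 1 library per group. A response to the compound is a candidate explanation, found and tested on the same data, and solvent effects or handling that differed between the groups were not tested.

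More genes passed with the replicate number as a block. The share of within-group variance of log2 CPM between replicate numbers was 73.0%, where 50% would be found without pairing, so differences shared by same-numbered libraries may account for the gain. The genes at 0 in one group and counted in all libraries of the other numbered 2 in the real split and 2 in the highest of the other 9 splits, so estimated counts that switch at random between overlapping transcripts could give them.

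The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. For genes changed, 1 split gave as many (4, highest other 2), over 2-fold 3 splits (2, highest other 2), and for list members 1 split (1, highest other 0). For lists 6 splits gave as many as the real 5, with 14 as the highest other, and for DNA damage response lists all 10 (0, highest other 2). The splits with both replicate 1 libraries together called 9 to 14 lists, which points to a structure of the samples. Of the 4 splits that part every pair, also too few, 1 gave as many genes with the block (93, highest other 1), 1 as many lists (7, highest other 3) and 4 as many DNA damage response lists (0, highest other 0).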
